A study of Mus musculus with 3 samples.

How the data were processed

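RNA of L929 cells, a mouse fibroblast line, was measured in 3 samples. The series compares cells with a knockdown of Rrm2 with control cells, each read by CBTi-seq and by a method that targets the 3' ends of transcripts. Per the labels' protocols, individual cells were picked with a capillary into lysis buffer, reverse transcribed from an oligo dT primer with a template switch, and amplified over 20 PCR cycles. The same protocol text stands with all 3 samples, so how the 3' libraries differed in preparation is not given in the sources used here.

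The authors deposited whole-number counts per gene and column, with no normalization. The CBTi-seq sample is a table of 20 columns, 10 named control and 10 named knock, with gene symbols in 20717 rows and a name that refers to UMIs (molecular identifiers). Each of the 3' samples is a table of 8 numbered columns with 55402 Ensembl IDs. Per the submitters' processing notes, FastQC, Picard and STAR 2.7.11b were used, and the builds GRCm38 and GRCh38 are named without their roles. The counting tool, its use of strand, its filters, and whether the 3' tables hold reads or UMIs are not given in the sources used here.

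Of the 3' IDs, 55141 matched a gene in the GENCODE vM21 annotation (GRCm38), and the rows without a match held 0.0194% of the counts of the library labelled control and 0.0329% of those of the library labelled knock. Rows with the same symbol were added up. Of the CBTi-seq symbols, 97.4% had a partner among the 3' symbols, and these held 98.8% of the CBTi-seq counts. They were 36.5% of the 3' symbols, with 94.6% of the 3' counts. Every gene of the CBTi-seq table has at least 1 count, so genes found by the 3' method alone have no row there and stayed out of the comparison of assays. Among CBTi-seq symbols, 22 had been turned into dates, with 0.206% of the counts; these were kept in the totals and not named. Coordinates are from GENCODE vM21, 1-based.

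There was 1 sample per 3' library and 1 for both CBTi-seq groups, and columns of a sample are not replicates. No test, p-value or count of changed genes was therefore made, and the differences have no replicate check. Counts were summed over the columns of a group, all of which held at least 500 counts, and scaled to the total of all gene counts (CPM, in the usual sense). Levels are given with exact Poisson 95% intervals and ratios with exact conditional (Clopper-Pearson) 95% intervals. These cover counting error only and leave out variation between columns, so in both assays they are narrower than the spread of the columns would give. Where the counts are reads and not molecules, they are too narrow for counting error as well. A gene was called 2-fold apart by size alone, with a mean level of at least 50 CPM and a log2 ratio of at least 1 in size.

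Before the data were examined, 24 gene lists and 8 lists of markers of other cell types were fixed. A list's median log2 ratio over members at 20 CPM or more was placed among 10000 random lists of the same size, matched on mean level in 10 bins, where at least 5 members were measured. A list is said to stand apart beyond the central 95% of these random lists, which describes these libraries and no more. The rule for named genes was fixed then too. It took Rrm2, the 10 largest ratios in each direction and up to 4 members per list with the largest ratios. For the largest ratios, a gene needed 50 CPM on average, a count in at least 25% of the columns of the higher group, and the same direction without its highest column there. Unnamed gene models were left out. The same limits gave the 10 largest ratios between assays in each direction. Towards CBTi-seq, genes with no 3' count came first, ordered by level. Genes named outside this rule are said to be so.

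Detection was compared after thinning each column to 50000 counts, which left out 1 CBTi-seq control column. Alternatives were the mean of CPM over columns, TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0), totals without mitochondrial and ribosomal protein genes, other level limits, thinning, and 2 filters on columns. Other steps used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

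The calculation was tested on simulated counts drawn from the real levels and totals, with 200 genes altered. For CBTi-seq, the log2 ratio was recovered with a median absolute error of 0.06 for the 100 genes altered by 1 and 0.07 for the 100 altered by 2, and the interval held the true ratio for 95.5% of the 200. For the 3' tables the errors were 0.03 and 0.06, and the interval held the true ratio for 98.5%. None of the unaltered genes came out 2-fold apart (0 of 5196 and 0 of 2461). Each simulated column of a group was drawn from the same levels with counting error alone, so these figures check the calculation only. They do not cover variation between columns or a limit on counts. Over genes at 50 CPM or more, the median coefficient of variation beyond counting error was 33.1% and 19.9% in CBTi-seq control and knock columns. It was 12.2% and 9.93% in the 3' libraries labelled control and knock.

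The alternative splicing named in the title of the series was not analysed here, since the tables give counts per gene.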

Results

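The series asked how knockdown of Rrm2, a subunit of ribonucleotide reductase, appears in L929 fibroblasts read by CBTi-seq and by a 3' method. The CBTi-seq sample held 10 columns named control and 10 named knock, with 41570 to 846819 and 153051 to 735871 counts. They are called control cells and knock cells here after the protocol text, though their names do not call them cells. The 8 columns of the 3' library labelled control held 399393 to 2496457 counts, and the 8 of the library labelled knock 814960 to 1973137. Over the summed columns, 3 counts corresponded to 0.777 and 0.855 CPM in the CBTi-seq control and knock cells, and to 0.424 and 0.327 CPM in the 3' libraries labelled control and knock. Each 3' library was 1 sample and both CBTi-seq groups were columns of 1 sample, so no difference below was tested against replicates.

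Rrm2 was lower in the CBTi-seq cells named knock and higher in the 3' library labelled knock. The gene (ENSMUSG00000020649) is protein coding and lies on chromosome 12 from 24708241 to 24714146 on the plus strand in GRCm38. In CBTi-seq it stood at 480.9 CPM in the control cells (95% interval 459.2 to 503.2, from 1857 counts) and at 350.1 CPM in the knock cells (330.8 to 370.3, from 1228 counts). The knock level was 72.8% of the control level, with an interval of 67.7% to 78.3%. The columns overlapped, with 356.1 to 652.2 CPM in the control cells and 282.7 to 489.4 CPM in the knock cells.

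In the 3' tables Rrm2 went against the label. It stood at 39.1 CPM in the library labelled control (34.6 to 43.9, from 276 counts) and at 148.1 CPM in the library labelled knock (140.3 to 156.2, from 1357 counts). That is 3.79-fold higher in the library labelled knock, with an interval of 3.33 to 4.33. The columns did not overlap, with 29.2 to 49.6 CPM against 123.0 to 172.9 CPM. Columns of a 3' library were much alike and are not replicates, so this is no replicate check of the difference between the libraries. The 3' libraries are therefore named by their labels throughout, and each 3' direction below rests on labels that Rrm2 does not bear out.

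**Figure D1:**
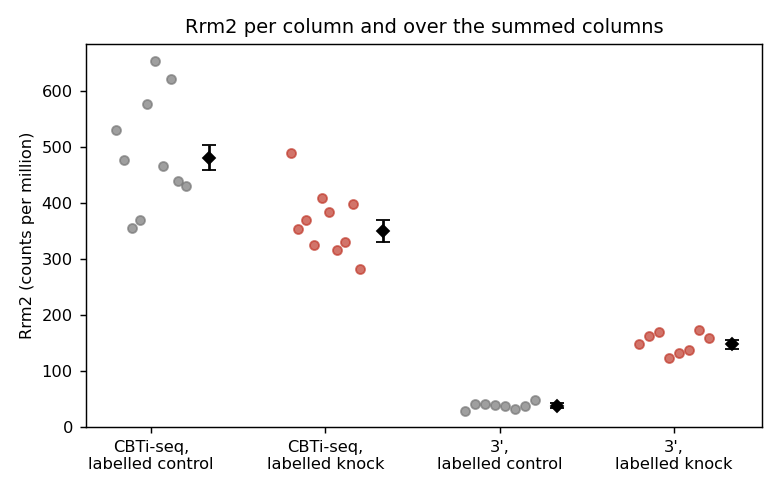
Rrm2 in CPM (y axis, from 0) for each column of the 4 groups (x axis). Circles are columns, and diamonds are the summed columns with exact Poisson 95% intervals. The summed level was 480.9 against 350.1 CPM in CBTi-seq and 39.1 against 148.1 CPM in the 3' libraries, control first.

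The other subunits of the enzyme also differed in the 3' libraries. Rrm1, the large subunit, was at 23.9 CPM in the library labelled control and 98.99 CPM in the one labelled knock, a log2 ratio of 2.05 (1.81 to 2.30). Rrm2b, the p53-inducible small subunit, was at 160.5 and 94.8 CPM, a log2 ratio of -0.76 (-0.89 to -0.63). In CBTi-seq the log2 ratio of Rrm1 was 0.18 (0.01 to 0.35), and that of Rrm2b was -0.37 with an interval that included 0 (-0.85 to 0.11). Rrm2b, and Rrm1 in CBTi-seq, were chosen after their values were seen.

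In CBTi-seq, the knock cells had more p53 target and stress response RNA and less RNA of hypoxia, glycolysis and cholesterol synthesis genes. Of 5243 genes at 50 CPM or more, 18 were at least 2-fold higher in the knock cells and 35 at least 2-fold lower, and the median log2 ratio was -0.01. With each column thinned to the same depth the counts were 35 and 124, and with each column weighing the same they were 18 and 66. Without knock column 10, 54 genes were lower. Of the genes at least 2-fold apart, 34.0% were higher. This share was 21.4% with equal weights and 22.0% after thinning. It was 39.6% with median-of-ratios factors (21 higher and 32 lower) and 42.9% with TMM factors (21 and 28). Of the 23 lists with enough members, 7 stood above the random lists and 5 below. For lists of genes drawn at random, 1.15 in all would lie outside. Genes of a real list can vary together between columns, so 1.15 is not the number to be had by chance between groups of cells.

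The p53 target genes were the list farthest above, with a median log2 ratio of 0.50 and 16 of 22 members higher. Cdkn1a, an inhibitor of cyclin-dependent kinases, was at 192.9 CPM in the control cells and 379.5 CPM in the knock cells, a log2 ratio of 0.98 (0.85 to 1.11). Zmat3 had a log2 ratio of 1.26 (1.01 to 1.52), and Plk2 of 1.05 (0.83 to 1.27). Genes of the integrated stress and unfolded protein response had a median of 0.27, with 30 of 37 higher. Among them the transcription factor Ddit3 had a log2 ratio of 0.89 (0.74 to 1.04), Chac1 of 0.97 (0.77 to 1.16) and Herpud1 of 0.80 (0.68 to 0.91), while Vldlr was lower at -0.95 (-1.19 to -0.72).

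Genes of dNTP and nucleotide synthesis were higher too, by a median of 0.17 with 26 of 33 members higher. Thymidylate synthase (Tyms) had a log2 ratio of 0.51 (0.36 to 0.65), and Tk1 of 0.56 (0.35 to 0.77). S phase genes had a median of 0.17 with 32 of 45 higher, led by Ccne1 at 0.83 (0.56 to 1.11), while Dtl was lower at -0.71 (-0.94 to -0.48). All 31 measured proteasome genes were higher, by a median of 0.22, and 21 of 24 chaperones, by 0.19. Senescence and secreted cytokine genes had a median of 0.17 with 9 of 14 higher. After thinning, S phase, cytokine, proteasome and chaperone genes no longer stood apart, and with equal weights per column S phase, cytokine and chaperone genes did not. The cytokine genes stood apart in none of the 6 alternatives that placed lists again, among them leaving out control column 1, the shallowest. The chemokine Cxcl1 had the highest CBTi-seq ratio of the genes named for that assay. It was at 21.8 CPM in the control cells and 177.9 CPM in the knock cells (8.18-fold, 6.50 to 10.4). Its columns ranged from 0 to 94.8 CPM and from 25.8 to 406.3 CPM. Lcn2, a secreted iron-siderophore binding protein, was at 93.5 and 230.7 CPM (log2 ratio 1.30, 1.12 to 1.49).

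Lower in the knock cells were 20 of 21 cholesterol synthesis genes, by a median of -0.63. Of 26 glycolysis and hypoxia genes 23 were lower, with a median of -0.43. Carbonic anhydrase 9 (Car9) was at 298.3 and 94.1 CPM (log2 ratio -1.66, -1.85 to -1.49), Bnip3 at 413.8 and 177.6 CPM, and Ndrg1 at 233.3 and 103.5 CPM. The glycogen branching enzyme gene Gbe1 had the lowest ratio among the genes ranked by size (log2 ratio -2.23, -2.61 to -1.86), and ceruloplasmin (Cp) was at 159.5 and 39.9 CPM. Immediate early genes were lower by a median of -0.36, with 20 of 24 lower, among them Fos at -1.72 (-2.21 to -1.24). Autophagy and lysosome genes had a median of -0.18 with 22 of 32 lower. Extracellular matrix genes had a median of -0.19 with 17 of 23 lower, led by Col1a2 at -1.26 (-1.54 to -0.98). G2 and M phase genes did not stand apart, with a median of -0.03. It was above 0 with equal weights per column, after thinning and under TMM and median-of-ratios factors, while under both corrections for UMI collisions the list stood below the random lists, at -0.07 and -0.10. Nor did the 79 ribosomal protein genes stand apart, of which 73 were higher by a median of 0.13, but with equal weights per column their median was 0.03 and stood below the random lists.

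In the 3' libraries, cell cycle, replication-dependent histone, cytokine and cytoskeletal genes were higher in the library labelled knock, and ribosomal protein genes were lower there. Of 2826 genes at 50 CPM or more, 377 were at least 2-fold higher in the library labelled knock and 128 at least 2-fold lower. The median log2 ratio of these genes was 0.14, and TMM factors shifted it by -0.15, median-of-ratios factors by -0.16, and totals without mitochondrial and ribosomal protein genes by -0.13. Such a shift moves a list and its random lists alike, so the lists below are placed relative to it. Of the genes at least 2-fold apart, 74.7% were higher. This share was 56.7% with TMM factors (270 higher and 206 lower) and 56.5% with median-of-ratios factors (270 and 208). Without mitochondrial and ribosomal protein genes in the total it was 60.3% (381 and 251). Of the 24 lists, 11 stood above the random lists and 2 below, where 1.2 in all would lie outside for lists of genes drawn at random. The limit given for CBTi-seq holds here too.

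All 8 measured replication-dependent histone genes were higher in the library labelled knock, by a median of 2.72. By the protocol text the primer was oligo dT, so this ratio does not measure RNA of these genes without a poly(A) tail. G2 and M phase genes had a median of 1.44 with 40 of 41 higher, and S phase genes of 1.12 with 27 of 29 higher. Mki67, a marker of cycling cells, was at 6.93 CPM in the library labelled control and 66.1 CPM in the one labelled knock (log2 ratio 3.25, 2.83 to 3.70). Cenpf had a log2 ratio of 3.26 (2.98 to 3.55) and the maintenance DNA methyltransferase gene Dnmt1 of 3.16 (2.81 to 3.52). All 7 measured senescence and cytokine genes were higher, by a median of 1.90. The chemokine gene Ccl7 was at 25.6 and 632.0 CPM (log2 ratio 4.63, 4.41 to 4.85). Of the myofibroblast and actin cytoskeleton list, 17 of 18 genes were higher, by a median of 1.13. Lmna, a gene of the nuclear lamina and not of actin, was at 237.9 and 1091 CPM. The serotonin receptor gene Htr1d had the highest log2 ratio, 6.16 (5.63 to 6.74), with 4.10 and 292.7 CPM.

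Mitochondrially encoded genes were higher in the library labelled knock, all 9 of them, by a median of 0.93. They held a median of 0.968% of the counts of a column in the library labelled control and 1.70% in the one labelled knock. Nuclear-encoded genes of oxidative phosphorylation (49 of 69 higher, median 0.33), splicing factors (43 of 53, median 0.43), proteasome genes (24 of 30, median 0.40), extracellular matrix genes (11 of 15, median 0.64) and p53 targets (12 of 16, median 0.73) also stood above. None of these 5 lists stood apart after thinning, splicing factors did not without column 2 of the library labelled control, and p53 targets, extracellular matrix and proteasome genes did not with members from 50 CPM. Cdkn1a was at 294.0 and 566.9 CPM (log2 ratio 0.95, 0.87 to 1.02), while the p53 target Gadd45a was lower at -1.40 (-1.61 to -1.21). The value of Cdkn1a in the 3' libraries was looked up after it was named in CBTi-seq.

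Ribosomal protein genes were lower in the library labelled knock in 69 of 72 cases, by a median of -0.51, and held a median of 16.3% of its counts against 24.4% in the library labelled control. Rpl5 was at 5254 and 2011 CPM (log2 ratio -1.39, -1.41 to -1.36). Stress and unfolded protein response genes had a median of -0.31 with 25 of 34 lower, among them Dnajb9 at -1.09 (-1.20 to -0.98). Rasgrf1, a Ras exchange factor gene, was at 1645 and 67.0 CPM (log2 ratio -4.62, -4.74 to -4.50). The snoRNA host genes Snhg12, Snhg1 and Snhg5 were among the 10 lowest ratios, with log2 ratios of -3.69 (-3.95 to -3.44), -2.66 (-2.83 to -2.50) and -2.44 (-2.71 to -2.18). Hypoxia genes went both ways. Ero1l was lower at -2.40 (-2.56 to -2.25), Ndrg1 at -1.92 (-2.12 to -1.73) and Car9 at -1.68 (-2.03 to -1.34), while 14 of the 20 measured members of the glycolysis and hypoxia list were higher, by a median of 0.43 that did not stand apart.

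**Figure D2:**
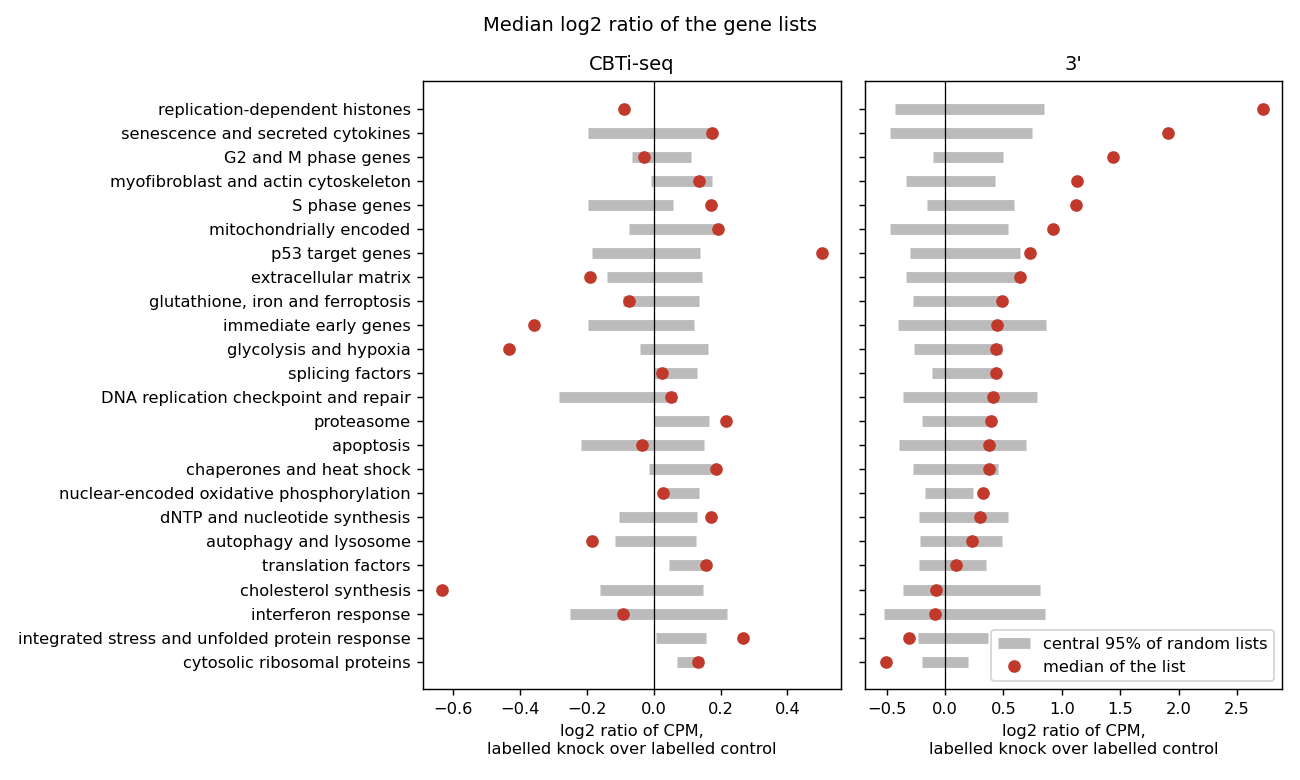
Median log2 ratio of CPM, labelled knock over labelled control (x axis, with a different scale in each panel), for the 24 gene lists (y axis) in CBTi-seq and in the 3' libraries. Points are list medians and grey bars the central 95% of random lists matched on level, absent where fewer than 5 members were measured. Cholesterol synthesis lay lowest in CBTi-seq at -0.63, and replication-dependent histones highest in the 3' libraries at 2.72.

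Across genes, the CBTi-seq and 3' contrasts were nearly unrelated. For 2195 genes at 50 CPM or more in both assays, Pearson's r of the log2 ratios was 0.03 and Spearman's rho 0.02, and 52.7% had the same sign. Genes are not independent replicates, so no p-value is given. Cdkn1a, Zmat3, Lcn2, Cxcl1 and Ccl7 were higher in the knock-labelled group of both assays, and Car9 and Ndrg1 lower in both, as far as the 3' labels hold. These genes were named for large ratios, so they do not show how often the directions match. Of the genes at least 2-fold apart in both assays, Lcn2 was higher in both and Ndrg1 lower in both. Unrelated contrasts would give 0.61 and 0.19 such genes. Gm47015 and Pcyt2 were lower in the CBTi-seq knock cells and higher in the 3' library labelled knock, where 0.76 would be found. Numbers this small show no match between the contrasts. Gm47015 and Pcyt2 were named after their values were seen. Rrm2, Rpl5, Ddit3 and Herpud1 differed in direction. How the counting treated overlapping genes and near-identical copies is not given, which leaves some of these values uncertain. Rrm1, Dnmt1, Rpl5, Col1a2, Snhg1, Snhg5 and Snhg12 overlap an annotated gene on the same strand, and Cdkn1a, Mki67, Cenpf, Tk1, Ddit3, Herpud1, Dnajb9, Gadd45a, Car9, Ndrg1, Bnip3 and Cp on the opposite strand, while histone and ribosomal protein genes have close copies. Rrm2 overlaps none.

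**Figure D3:**
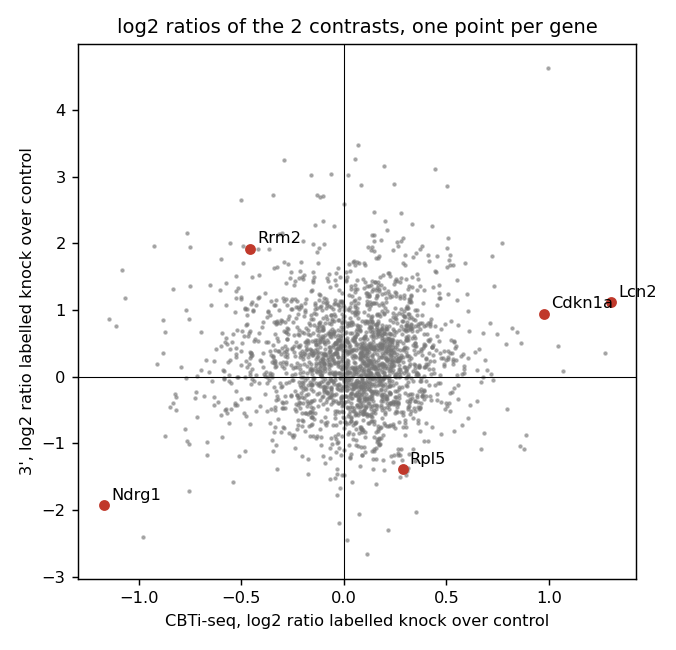
log2 ratio of CPM, labelled knock over labelled control, in CBTi-seq (x axis) and in the 3' libraries (y axis), with a point for each of 2195 genes at 50 CPM or more in both. Named genes are in red. Spearman's rho over these genes was 0.02, and Rrm2 lay at -0.46 in CBTi-seq and 1.92 in the 3' libraries.

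The levels of genes in the assays were related over the whole range and less so among genes with a mean level of 20 CPM or more. For 20186 shared genes, each with at least 1 CBTi-seq count, Pearson's r of log2(CPM + 1) was 0.76 and Spearman's rho 0.72, across genes. For 7598 genes at 20 CPM or more on average over the assays, r was 0.31 and rho 0.40. That limit narrows the range and keeps genes with a level in only 1 assay, which by itself can lower r. With a count in both assays as well, r was 0.40 over 7267 genes. Rrm2 itself was at 418.6 CPM over all CBTi-seq columns and 100.6 CPM over all 3' columns.

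Among genes at 50 CPM or more in CBTi-seq, 274 of 5198 had no count in any of the 16 columns of the 3' tables. Among the highest of these were the ribosomal protein genes Rpl35 and Rpl13, the MHC class I light chain gene B2m, Rpl35a, Rps3a3, Eif2s2, Anxa1, Gsto1 and Chchd2. B2m was at 728.1 CPM in CBTi-seq, at least 3939-fold above the 0.185 CPM that 3 counts make over the 3' tables. Among genes with a row in the CBTi-seq table, which lists none without a count, the 10 with the largest ratios towards the 3' tables had between 1 and 18 CBTi-seq counts. Grik3 was at 418.7 CPM there with 1 CBTi-seq count (log2 ratio of CBTi-seq to 3' level -11.59, -16.90 to -9.11), Pde1c at 807.8 CPM with 2, and Trim30a at 1179 CPM with 18. The dystrophin gene Dmd was at 214.9 CPM with 1 CBTi-seq count. These 10 genes span between 56169 bases (Trim30a) and 2257272 bases (Dmd) of the genome, with longest transcripts of 3771 and 14910 bases for these genes. Counts per gene do not show whether the 3' counts lie in exons, so these values may not be levels of mature transcripts.

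In CBTi-seq no gene passed 638 counts in any column. The highest count of a column was between 399 and 638, while column totals differed 20.4-fold. In the 3' tables the highest count was between 10578 and 67257. The 20 most abundant genes of a column held a median of 2.76% and 2.80% of the counts of the CBTi-seq control and knock cells, and 18.1% and 14.7% in the 3' libraries labelled control and knock.

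**Figure D4:**
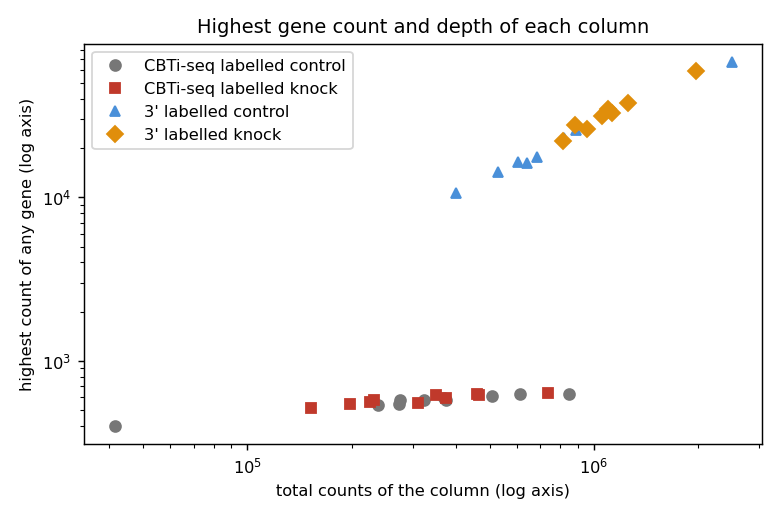
Highest count of any gene (y axis, log scale) against the total counts of the column (x axis, log scale), with a point for each column of the 4 groups. The highest count stayed between 399 and 638 in CBTi-seq and between 10578 and 67257 in the 3' tables.

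Thinned to 50000 counts per column, more genes were detected in a CBTi-seq column than in a 3' column. The medians were 9221 genes (8698 to 9403, 9 columns) in the control cells and 8828 (8456 to 9420, 10 columns) in the knock cells. They were 6947.5 (6754 to 7079) and 7614.5 (7510 to 7709) in the 8 columns each of the 3' libraries labelled control and knock. Without thinning the order was lost, at 13073.5 and 12784.5 genes in CBTi-seq and 13185 and 14845.5 in the 3' libraries, whose columns were deeper. Thinning to equal totals does not equalise how the counts are spread, since the most abundant genes held a smaller share of them in CBTi-seq, so the order is not a measure of sensitivity alone. Genes were also counted over unlike sets, of 20716 symbols in CBTi-seq and 55295 in the 3' tables. What a column holds is not labelled in either assay, so the columns of the assays may be unlike too.

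Markers of other cell types were checked for RNA of other cells. In CBTi-seq control and knock cells the summed levels were 182.8 and 107.5 CPM for macrophage markers, 489.1 and 497.6 CPM for adipocyte markers, which were mostly Fabp4 and Pparg, and 40.4 and 61.6 CPM for skeletal muscle markers. Epithelial (6.47 and 3.71 CPM), endothelial (1.29 and 0 CPM), T cell (2.59 and 0.855 CPM), erythroid (2.85 and 1.71 CPM) and neuronal markers (0.777 and 1.14 CPM) were lower. The 0 for endothelial markers allows up to 0.855 CPM by the 3 counts named above. In the 3' libraries labelled control and knock the sums were 375.8 and 310.2 CPM for macrophage, 194.8 and 122.7 CPM for epithelial, 142.8 and 469.4 CPM for adipocyte, 43.7 and 51.5 CPM for neuronal, 34.5 and 39.7 CPM for endothelial, 21.1 and 41.7 CPM for skeletal muscle, 13.0 and 16.5 CPM for T cell, and 0 and 2.84 CPM for erythroid markers, where the 0 allows up to 0.424 CPM. Fabp4, a fatty acid binding protein gene, made up most of the adipocyte sum, at 132.3 and 456.2 CPM.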

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

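Except the comparison of the slope of CBTi-seq on 3' levels, the tests in this part were chosen after the results they bear on, or values close to them, had been seen.

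Rrm2 differed in direction between the assays, with a log2 ratio 2.38 higher in the 3' libraries than in CBTi-seq, which was not tested, since there are no replicates. Scaling to totals is argued against, as the lowest 3' log2 ratio of Rrm2 under 3 other scalings was 1.77. A different share of cycling cells may account for it and stays open, because the 3' ratio of Rrm2 lay above that of 72.9% of 70 measured S, G2 and M phase genes, whose median was 1.32. Exchanged 3' labels stay open: genes 2-fold apart in CBTi-seq had a median 3' ratio, aligned to their CBTi-seq direction, 0.52 above matched draws, past the bound set against an exchange, but that bound was set aside after the value was seen, since the 14 higher and 14 lower genes had 3' medians of 0.84 and 0.85 that differ by -0.01. An effect of the knockdown itself, which the design names, also stays open and was not tested.

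The extracellular matrix list stood below the random lists in CBTi-seq and above them in the 3' libraries, with medians 0.84 apart, which was not tested; the 3' place was lost after thinning and from 50 CPM. The stress and unfolded protein response list did the opposite, with a 3' median minus the CBTi-seq median of -0.58, also not tested. Both differences rest on the 3' labels. Turning these would bring the lists to the same direction by construction, and would part the 4 lists that stood above the random lists in both assays as labelled: p53 targets (medians of 0.50 in CBTi-seq and 0.73 in the 3' libraries), S phase (0.17 and 1.12), senescence and cytokines (0.17 and 1.90) and proteasome (0.22 and 0.40). Each of the 4 lost its place in at least 1 assay after thinning.

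No gene passed 638 counts in any CBTi-seq column. Over the 20 columns the log count of the 20 most abundant genes went up with the log total by a slope of 0.384, against 1.14 for 2409 genes of intermediate level, and by 0.267 and 1.19 without the shallowest column. A limited number of distinct UMIs per gene may account for this and would compress ratios of abundant genes. It would also lower their share of the counts in deeper columns. Ribosomal protein genes held 10.9% of the counts in the shallowest CBTi-seq column (41570 counts) and 4.22% in the deepest (846819 counts). The cause of that difference was not tested. Counting of different parts of transcripts by the assays is argued against as the whole cause, since it would let counts go up with the total, and the 95% interval of the slope of 0.384 ended at 0.447; an earlier test, the slope of CBTi-seq on 3' levels, was undecided, with a difference of -0.12 in the 200 highest genes and an interval of -0.35 to 0.11 around the limit of -0.2. No biological explanation was tested.

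Of the 274 genes at 50 CPM or more in CBTi-seq with no count in any 3' column, 98.9% overlap another annotated gene on either strand (exact 95% interval 96.8% to 99.8%), against 52.5% of 4924 genes with a count (51.1% to 53.9%), a gap of 46.4 percentage points. A low level is argued against, since the share with no 3' count was 5.41% (exact 95% interval 4.17% to 6.88%) among genes of at least 200 CPM in CBTi-seq and 5.94% (5.03% to 6.95%) among those of 50 to 100 CPM, a ratio of 0.911. Counts in overlapping stretches left out of the 3' tables without regard to strand are a candidate explanation, found and tested on the same data. No biological explanation was tested.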

How the results depend on the processing

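Alternatives that leave out a column, correct for UMI collisions or need a count in both assays were chosen after seeing the data. Both filters on columns removed none, so they say nothing. Neither Rrm2 nor a list that stood apart changed sign. Of the values for Rrm2, counts, correlations and detection under alternatives, 36 moved and 68 did not; of the list medians, 24 moved by more than the spread of random lists and 539 by less. Level limits and thinning change how many genes or counts enter; for the other shifts below the cause was not tested.

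The 3' log2 ratio of Rrm2 stayed between 1.77 and 2.05. In CBTi-seq it was -0.46, -0.35 after thinning, and -0.60 corrected for collisions with an assumed 700 UMIs.

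Genes at least 2-fold higher and lower in CBTi-seq (18 and 35) were 45 and 203 from 20 CPM, 0 and 2 from 200 CPM, 2929 and 4239 with no minimum, and 35 and 124 after thinning, with 66 lower under equal weights per column. In the 3' libraries (377 and 128) they were 986 and 324 from 20 CPM, 61 and 44 from 200 CPM, and 6079 and 3454 with no minimum. Lower genes were 206 with TMM, 208 with median-of-ratios factors, and 251 without mitochondrial and ribosomal protein genes in the total. After thinning, 3 CBTi-seq lists stood above the random lists in place of 7, and 6 3' lists in place of 11.

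Pearson's r between assays (0.76) was 0.31 from 20 CPM and 0.40 with a count in both assays as well. Median genes detected per column are given for CBTi-seq control and knock, then for the 3' libraries labelled control and knock. They were 13073.5, 12784.5, 13185 and 14845.5 without thinning, and 6579, 6321, 4153 and 4696 from 2 counts. At 25000 counts they were 7241, 6998, 5086.5 and 5648.5.

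Depth limits single columns most. In the shallowest, a CBTi-seq control column of 41570 counts, 3 counts make 72.2 CPM. Leaving out any 1 column kept the log2 ratio of Rrm2 between -0.51 and -0.39 in CBTi-seq and between 1.87 and 1.99 in the 3' libraries. It moved the CBTi-seq count of lower genes to between 33 and 54, the latter without knock column 10. No paired analysis was possible because the labels pair no samples or columns.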

Other observations

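The values of this part on snoRNA host genes, variation over columns and transcript length were chosen after the data were examined.

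Gene lists fixed in advance that the text has not described did not stand apart from random lists in the main setting. In CBTi-seq, 34 of 39 translation factor genes were higher in the knock cells by a median of 0.16, and 12 of 14 mitochondrially encoded genes by 0.19. Splicing factors (0.03, 36 of 67 higher), nuclear-encoded oxidative phosphorylation (0.03, 40 of 75) and replication checkpoint and repair genes (0.05, 15 of 30) had medians close to 0. So did myofibroblast and actin cytoskeleton (0.13, 17 of 23) and interferon response genes (-0.09, 3 of 8). Glutathione and iron (-0.07, 13 of 31) and apoptosis genes (-0.04, 8 of 19) did as well. Some of these CBTi-seq lists did stand apart under alternatives. Interferon genes stood below after thinning (-0.40), glutathione genes below with equal weights per column (-0.11), after thinning (-0.19) and with 700 assumed UMIs (-0.14), and oxidative phosphorylation genes below from 50 CPM (0.03). Mitochondrially encoded genes stood above without control column 1 and under both corrections for UMI collisions (0.20 to 0.21), repair genes above without control column 1 (0.09), and translation factors above with equal weights (0.19). Of the replication-dependent histone genes 4 were measured, too few for a place among random lists. In the 3' libraries, medians were 0.30 for dNTP synthesis (20 of 25 higher), 0.41 for replication checkpoint and repair (10 of 13), 0.49 for glutathione and iron (15 of 20), 0.37 for chaperones (17 of 23), 0.44 for immediate early genes (7 of 9), 0.23 for autophagy and lysosome (18 of 25), 0.38 for apoptosis (8 of 11), 0.10 for translation factors (21 of 35), -0.08 for interferon response (3 of 7) and -0.07 for cholesterol synthesis (4 of 11).

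The snoRNA host genes, whose introns carry small nucleolar RNAs, were put together as a list because several had low ratios in the 3' libraries, so their place there is no independent evidence. In the library labelled knock 10 of 13 measured were lower, by a median of -0.75. Zfas1 was at 551.6 CPM in the library labelled control and 112.7 CPM in the one labelled knock, and Gas5 at 169.2 and 40.7 CPM. In CBTi-seq the median of 15 measured members was 0.11, at percentile 93.2 of the random lists, with Zfas1 at 149.4 and 173.4 CPM. Zfas1, Gas5, Snhg1, Snhg5 and Snhg12 overlap other annotated genes on the same strand.

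Columns of a 3' library were more alike than columns of CBTi-seq. The share of counts in G2 and M phase genes had a coefficient of variation over columns of 38.6% and 22.4% in the CBTi-seq control and knock cells, and of 4.25% and 3.65% in the 3' libraries labelled control and knock, where counting error alone gives 2.66% and 1.43%. The 3' value was 0.163 times the CBTi-seq value for the groups labelled knock and 0.110 times for those labelled control. The protocol text that stands with all 3 samples describes the picking of individual cells. Neither the numbered 3' columns nor the CBTi-seq columns are labelled as cells, so what a column holds stays open in both assays.

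The ratio of CBTi-seq to 3' level went with the length of the longest annotated transcript, with a Spearman's rho of 0.28 across 3970 genes. Its median log2 value was -0.04 in the 993 genes with the shortest transcripts and 1.20 in the 992 with the longest.

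The median and the summed counts of a list differed in sign for G2 and M phase, histone, glutathione and apoptosis genes and adipocyte markers in CBTi-seq, and for interferon, glutathione, translation factor and cholesterol synthesis genes and neuronal markers in the 3' libraries. None of these medians stood apart in the main setting, and the histone list in CBTi-seq and both marker lists had too few measured members to be placed.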
